A study of Neurospora crassa with 18 samples.

How the data were processed

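Total RNA was extracted with TRIzol from mycelium and sequenced on a BGISEQ-500, per the labels' protocols. The 18 samples were assigned to 6 groups of 3 from their titles: wild type, cax-4 knockout and complemented strain, each with and without ketoconazole. The genotype entry of the complemented samples names a different number of the gene from sample to sample and was not used. Clean reads were mapped to the OR74A reference from FungiDB and expressed as FPKM by the authors, per the series text. HISAT2 2.0.4 and Bowtie2 2.2.5 are named in the submitters' processing notes without a role, and the counting program is not given in the sources used here.

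One deposited table was used, with 11284 rows, of which 9458 carried values and 1826 were blank in every library, among them 208 rRNA, 427 tRNA and 489 protein-coding rows. The deposited expected counts, between 76.1% and 78.0% of them whole within 0.005, were estimated by the authors for each gene and library without normalization. The deposited FPKM values were scaled by the authors to transcript length and mapped reads. Log2 fold changes and q values of the authors' own DESeq2 comparisons also stand in the table, per the file headers; they served only to check the orientation of columns and are not reported. A further 18 TPM columns and 18 group-average columns were not analysed here. Symbols came from the deposited table and from a reference that held 9433 of its gene identifiers, 4113 of them with a symbol. Start and end positions are those of the deposited table and linkage groups those of the NC12 assembly of strain OR74A; 79.3% of the deposited spans equal that reference's. Another gene on the same strand overlapped 1574 genes (16.6%), whose counts are uncertain because reads of one can be assigned to the other.

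Counts were rounded and fitted with edgeR 4.0.16 (limma 3.58.1, R 4.3.3), using TMM factors, the filterByExpr filter over the 6 groups, and a robust quasi-likelihood fit with 12 residual degrees of freedom. Total counts were 16444433 to 17729808 per library, and 8404 genes passed the filter. Between replicates the counts varied by a chi-square of 6.36 to 67.03 per degree of freedom, far more than counting error, so depth sets little of the precision. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 in its own comparison. Standard errors were computed from the fold change and the F statistic. For a group with no counts, fold bounds used a floor of 3 counts over the group, with library sizes scaled by the TMM factors.

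The comparisons were the drug response within each strain, each pair of strains without and with drug, and the difference of the drug response between knockout or complemented strain and wild type. A set of 18 gene lists was fixed before the files were opened and resolved by KEGG ortholog, symbol or description, with misannotated neighbours taken out afterwards without use of their values. They held 5 to 121 genes: late ergosterol, mevalonate, dolichol and N-glycan, endoplasmic reticulum folding, cell wall, drug efflux, conidiation, sexual development, ribosomal protein, oxidative phosphorylation, heat shock, antioxidant, iron uptake, fatty acid, sphingolipid, secreted glycoside hydrolase, GPI anchor and proteasome genes. Each list was tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. cax-4 was kept out of the list tests.

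The genes to name were set by a rule written beforehand: cax-4, and per main comparison the 6 highest and 6 lowest called genes with a mean of at least 10 FPKM, separate replicates and a symbol or description. Up to 4 members of each list with the smallest p were added, with all late ergosterol and dolichol genes allowed; comparisons of the complemented strain used the genes named for the knockout. The rule gave 1559 results of a gene in a comparison. The text prints 217 results, chosen after the values were seen, with preference for large changes and for genes that kept their direction on the FPKM scale; results of the complemented strain were further cut after it was seen which reversed. The text's genes are therefore steadier than those of the rule as a whole. Carotenoid genes and light markers lie outside the rule; the former were chosen after their values were seen.

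The edgeR steps were tested on simulated data drawn from the untreated wild-type means. Few genes were changed, up and down alike, so the test cannot show how the steps do where as many genes change as in the real comparisons. For the wild-type drug response, with 8140 genes run, 39 of 67 genes changed 1.5-fold were recovered (58.2%), 60 of 67 at 2-fold (89.6%) and 65 of 66 at 4-fold (98.5%), and 8 of 7940 unchanged genes were called. For the difference of the knockout's response, 22 of 67 (32.8%), 53 of 67 (79.1%) and 62 of 66 (93.9%) were recovered. In the simulated wild-type drug response camera called the 1 changed list and none of 20 unchanged lists. The first real fit was run before this test, which led to no change of it.

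Alternatives were DESeq2 1.42.0, RLE factors, no filter, the authors' FPKM filter, a fit on the compared groups only, the replicate number as a block, a 2-fold threshold, limma on log2 of FPKM with pseudocounts of 1 and 0.1, and leaving out each library. For lists they were camera with an estimated correlation, fry and the block. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.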

Results

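Messenger RNA levels were measured in mycelium of Neurospora crassa, a filamentous ascomycete, in 18 libraries that formed 6 groups of 3. The groups crossed 3 strains with the presence or absence of ketoconazole: the wild type, a strain in which cax-4 had been knocked out, and a knockout labelled as complemented with cax-4. The enzyme encoded by cax-4, dolichyl pyrophosphate phosphatase, recycles the lipid on which N-linked glycans are assembled. Ketoconazole is an azole antifungal that inhibits sterol 14-alpha-demethylase, the product of erg-11. Cultures had grown for 12 h before a further 12 h with 1 µg/mL of the drug or without it. Each library held between 16444433 and 17729808 counts, and 8404 genes were tested. Changes are given below as log2 fold changes ± their standard error (SE), and levels as TMM-scaled CPM ± SD with n = 3. Nothing in the labels shows that replicates came from separate cultures, so every p-value measures the spread between these samples, which can be technical.

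The targeted gene followed the strain labels in every library. cax-4 (NCU03718) spans 1390 bp on the minus strand of linkage group V, from position 2191710 to 2193099 as the deposited table gives it. Its level was 38.5 ± 0.982 FPKM (SD, n = 3) in the untreated wild type and 31.4 ± 1.41 FPKM with the drug. No count was assigned to it in any of the 6 knockout libraries. Against a floor of 3 counts over the group, this made the knockout at least 494-fold lower than the wild type without drug and at least 598-fold lower with it, on TMM-scaled counts. The complemented strain held 6.48 ± 0.498 FPKM without drug and 7.24 ± 0.406 FPKM with it, which was 16.8% and 23% of the wild-type level. It was lower than the wild type by edgeR in both conditions, with log2 fold changes of −2.01 ± 0.092 without drug and −1.63 ± 0.091 with it. Within the wild type the drug left cax-4 at −0.10 ± 0.082 (adjusted p = 0.297, edgeR), although on the FPKM scale limma called it lower at −0.29 (adjusted p = 0.00343). Within the complemented strain it was 0.28 ± 0.1 higher (adjusted p = 0.0213, edgeR), a call that DESeq2 lost (adjusted p = 0.0673) and that ended without control replicate 3 (0.0668) or drug replicate 2 (0.0608).

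**Figure D1:**
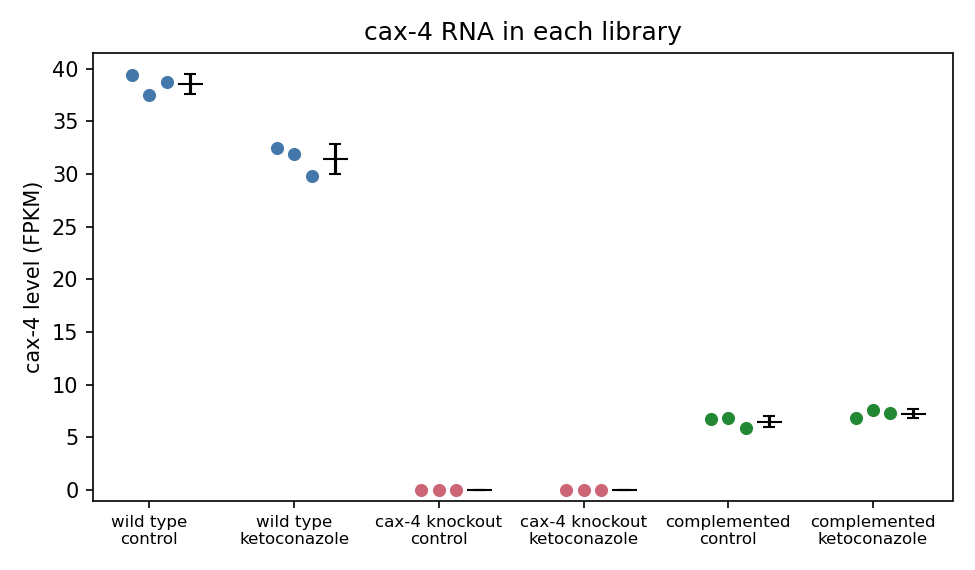
Level of cax-4 RNA in FPKM (vertical axis) in each of the 18 libraries, by strain and treatment, with the mean and SD of each group of 3 in black. The 6 knockout libraries lie at 0, and the complemented libraries lie between the knockout and the wild type.

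The drug and the strain both separated the libraries. The first principal component held 44.6% of the variance of log2 CPM and the second 24.5%. Wild-type controls had scores on the first component of −45.53 to −43.48, and their drug-treated counterparts 39.46 to 45.22. The complemented strain moved from between −25.72 and −20.18 to between 70.33 and 75.19. Knockout libraries moved less along this component, from between −55.36 and −50.08 to between 2.52 and 4.36. The next component, with 13.3% of the variance, set the drug-treated knockout apart, at −53.22 to −51.44.

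**Figure D2:**
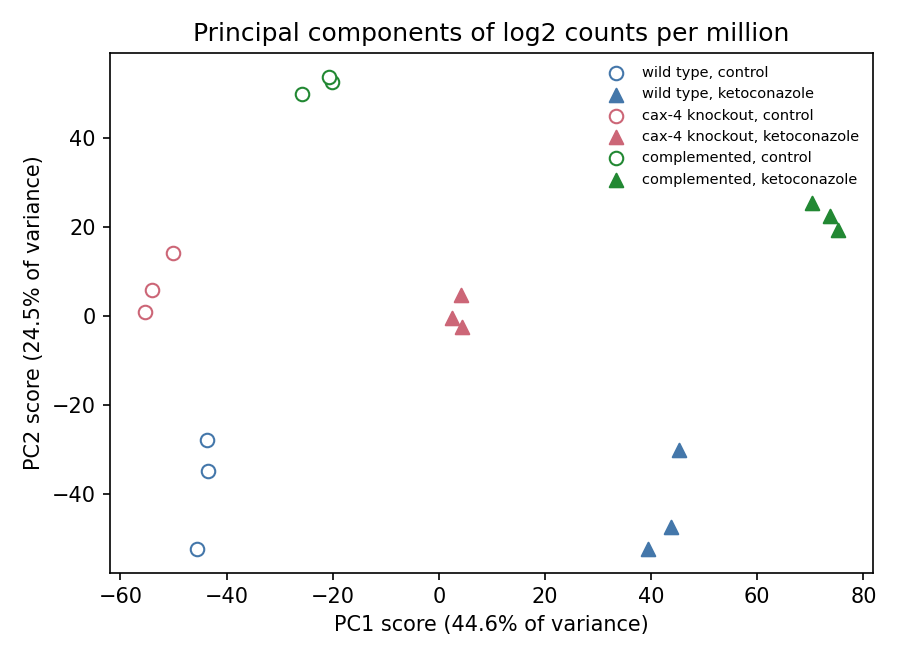
Scores of the 18 libraries on the first (horizontal) and second (vertical) principal component of log2 CPM, with strain shown by colour and ketoconazole by filled triangles. Drug-treated libraries lie to the right of the controls of their own strain, and the knockout moves least along this axis. The knockout also moves along the third component, which is not shown.

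The first comparison asked how the wild type responded to ketoconazole. Genes of the late ergosterol pathway, which turns squalene into ergosterol, rose together. erg-24 (NCU08762; linkage group III, 5237086 to 5238986), the sterol C-14 reductase that acts right after the azole target, rose from 129.9 ± 2.44 to 2092 ± 106 CPM, a log2 fold change of 4.01 ± 0.094 (adjusted p = 1.16e-15, edgeR). erg-6 (NCU03006; linkage group I, 8462585 to 8464460), the sterol C-24 methyltransferase, rose by 3.97 ± 0.133, from 129.8 ± 8.03 to 2028 ± 124 CPM. The azole target itself, erg-11 (NCU02624; linkage group I, 2956871 to 2959489), rose by 3.81 ± 0.104 to 3251 ± 386 CPM; it overlaps a neighbouring gene, so its value is uncertain. Smaller rises were called for erg-5 (NCU05278, 1.76 ± 0.118), erg-2 (NCU04156, 1.49 ± 0.108), the C-5 desaturases erg-3 (NCU06207, 1.45 ± 0.148, overlapping and uncertain; NCU04983, 1.28 ± 0.112), erg-1 (NCU08280, 1.23 ± 0.159), erg-25 (NCU06402, 1.13 ± 0.142) and erg-27 (NCU05991, 0.93 ± 0.151). Of the 14 tested members of the late ergosterol list, 10 rose and 1, erg-26 (NCU02693, −0.26 ± 0.068), fell. The list was higher than other genes by camera (adjusted p = 1.84e-04), but adjusted p = 0.214 with an estimated correlation.

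Earlier steps went the other way. Of 12 genes of the mevalonate list, 7 fell and none rose, among them erg-10 (NCU02571, acetyl-CoA acetyltransferase, −1.31 ± 0.087) and erg-14 (NCU00712, described as HMG-CoA reductase, −0.89 ± 0.096); camera gave adjusted p = 0.0163, and adjusted p = 0.371 with an estimated correlation. Fatty acid synthesis fell with them, in 4 of 6 genes with 1 risen. Acetyl-CoA carboxylase, acc-1 (NCU08535), fell by 3.17 on the log2 scale, from 500.0 ± 52.8 to 55.6 ± 9.03 CPM. The fatty acid synthase subunits cel-1 (NCU07308) and cel-2 (NCU07307) fell by 2.62 and 2.49, and the desaturase acds-1 (NCU05259) fell by 1.25. For this list camera gave adjusted p = 0.023, with adjusted p = 0.214 with an estimated correlation.

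The cell wall, GPI anchor, secreted glycoside hydrolase and sphingolipid lists were higher as sets by camera. In the cell wall list 41 of 56 genes rose and 5 fell (camera adjusted p = 1.71e-09, and adjusted p = 0.107 with an estimated correlation). The wall protein gene ncw-2 (NCU01752) went from 246.9 ± 3.66 to 3331 ± 147 CPM (3.75 ± 0.083), acw-9 (NCU06185) rose by 2.09 ± 0.092, and the glucanosyltransferase gene gel-3 (NCU08909) by 1.87 ± 0.095. GPI anchor synthesis had 13 risen and 1 fallen of 22 genes, with gid-1 (NCU08021, an inositol deacylase) at 1.40 ± 0.109; camera gave adjusted p = 0.00264, and adjusted p = 0.151 with an estimated correlation. Secreted glycoside hydrolases had 20 risen and 5 fallen of 42 genes (camera adjusted p = 6.32e-04, and adjusted p = 0.107 with an estimated correlation). Among them gh61-3 (NCU02916) rose by 4.79 ± 0.136 and the xylanase gh10-3 (NCU04997) by 4.25 ± 0.162. The sphingolipid list had 10 risen and 2 fallen of 17, with the desaturase gene dcd (NCU08927) at 1.52 ± 0.13 (camera adjusted p = 0.023, and adjusted p = 0.306 with an estimated correlation).

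Genes of the drug efflux list, which also holds regulators of the azole response such as sah-2, went both ways. The ABC transporters abc-5 (NCU05591) and abc-1 (NCU08056) rose by 2.86 ± 0.121 and 2.47 ± 0.123, while the major facilitator mdr-2 (NCU00754) fell from 96.4 ± 6.31 to 20.4 ± 5 CPM. Over the drug efflux list 14 of 24 rose and 7 fell (camera adjusted p = 0.0458, and adjusted p = 0.151 with an estimated correlation); the call was lost without drug replicate 3 (camera adjusted p = 0.0654). Conidiation genes had 14 risen and 6 fallen of 25 (camera adjusted p = 0.0322, and adjusted p = 0.454 with an estimated correlation), a call lost without control replicate 1 (0.0614) or drug replicate 3 (0.14). In that list mkr-1 (NCU08907) rose by 4.98 ± 0.423. Of 6 light-induced markers, 4 were called higher with the drug by edgeR, namely frq (1.69 ± 0.503, adjusted p = 0.00937), phr (1.93 ± 0.535, adjusted p = 0.00624), bli-4 (2.94 ± 0.896, adjusted p = 0.0113) and sub-1 (1.74 ± 0.283, adjusted p = 7.26e-05). Without drug replicate 3, bli-4 stood at 1.52 (adjusted p = 0.101, edgeR) and phr at 1.13, and without control replicate 3 frq stood at 2.73. In an edgeR fit on the wild-type groups alone frq and bli-4 were not called (adjusted p = 0.0946 and 0.0648). The blue-light receptor gene vvd varied between the wild-type control libraries, from 2.72 to 57.29 FPKM.

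The ribosomal protein, oxidative phosphorylation and heat shock lists were lower as sets by camera. Of 88 cytosolic ribosomal protein genes, 69 fell and 1 rose, by a median of −0.46 (camera adjusted p = 9.01e-11, and adjusted p = 0.295 with an estimated correlation); rap-1 (NCU03393) fell by 0.90. Oxidative phosphorylation had 54 fallen and 7 risen of 115 genes (camera adjusted p = 0.0061, and adjusted p = 0.447 with an estimated correlation). In the heat shock list 10 of 12 fell and 1 rose, with the mitochondrial chaperonin hsp60 (NCU01589) at −1.74 ± 0.162 and hsp70-5 (NCU08693) at −1.42 ± 0.106 (camera adjusted p = 0.00498, and adjusted p = 0.214 with an estimated correlation).

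The other lists were not called as sets by camera. In the dolichol and N-glycan list 12 of 24 genes rose and 5 fell (adjusted p = 0.142), with the dolichol kinase gene chol-14 (NCU03771) up from 28.1 ± 3.72 to 156 ± 11.6 CPM (2.47 ± 0.164) and the mannosyltransferase gene alg-9 (NCU04454) down by −1.06 ± 0.124. Folding genes of the endoplasmic reticulum had 11 risen and 4 fallen of 21 (camera adjusted p = 0.246): hac-1 (NCU01856), the transcription factor of the unfolded protein response, rose by 0.79 ± 0.075, and the chaperone grp78 (NCU03982) fell by 0.43. Antioxidant enzymes had 5 higher and 15 lower of 26 (camera adjusted p = 0.0768), iron uptake 1 higher and 2 lower of 5 (0.618), the proteasome 2 higher and 11 lower of 36 (0.277) and sexual development 7 higher and 1 lower of 14 (0.0901).

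Far larger single changes lay outside the lists. NCU00607, which has no described function, rose from 0.459 ± 0.469 to 1872 ± 63.7 CPM, and the pectate lyase gene ply-2 (NCU08176) from 0.0483 ± 0.0494 to 46.3 ± 7.42 CPM. The acid proteinase gene NCU04205 rose by 7.89 ± 0.193 and the dioxygenase gene NCU01849 by 6.60 ± 0.18. The cytochrome P450 gene ci-1 (NCU05001) rose to 4085 ± 154 CPM, while NCU12151, which overlaps it, had no count with the drug and was at least 737-fold lower; both values are uncertain. The L-amino-acid oxidase gene lao (NCU01066) fell by 4.90 on the log2 scale.

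Over the whole comparison edgeR called 5378 genes, 2602 higher and 2776 lower, and 1661 of them changed by more than 2-fold. On the FPKM scale the median of all genes lay at −0.18 and 34.4% of calls were higher, against 48.4% with TMM. Adjusted over the list alone, counts differed for the cell wall (41 higher and 6 lower), ribosomal (2 and 72), conidiation (15 and 6), sphingolipid (11 and 2), oxidative phosphorylation (7 and 52), proteasome (2 and 10) and glycoside hydrolase lists (19 and 4).

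The same treatment was then measured in the cax-4 knockout. With TMM, its late ergosterol genes did not move together: 4 of 14 rose and 4 fell. The list stood at camera adjusted p = 0.891, with a median of −0.11 and a mean of 0.04. On the FPKM scale, where the all-gene median lay at 0.31, the means of erg-7, erg-4, erg-5 and erg-26 were higher with the drug too. That of erg-5 went from 164.6 to 246.7 FPKM. Those of erg-2 (233.9 to 261 FPKM) and std-6 (57.73 to 58.34 FPKM) rose less, and their replicates were not separate. The means of erg-1, erg-25 and both copies of erg-3 were still lower there. erg-6 rose by 1.40 ± 0.122, from 90.96 ± 7.26 to 239.7 ± 19.8 CPM, the overlapping erg-11 by 1.17 ± 0.095 to 680.9 ± 4.93 CPM, erg-27 by 0.94 ± 0.159, and erg-24 by 0.38 ± 0.085 to 132.8 ± 8.11 CPM (adjusted p = 7.57e-04, edgeR). In contrast erg-1 fell by 0.87 (± 0.157), the overlapping NCU06207 copy of erg-3 by 0.72 (± 0.146), and erg-25 by 0.63 (± 0.141), the last not called on the FPKM scale (limma adjusted p = 0.0585).

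**Figure D3:**
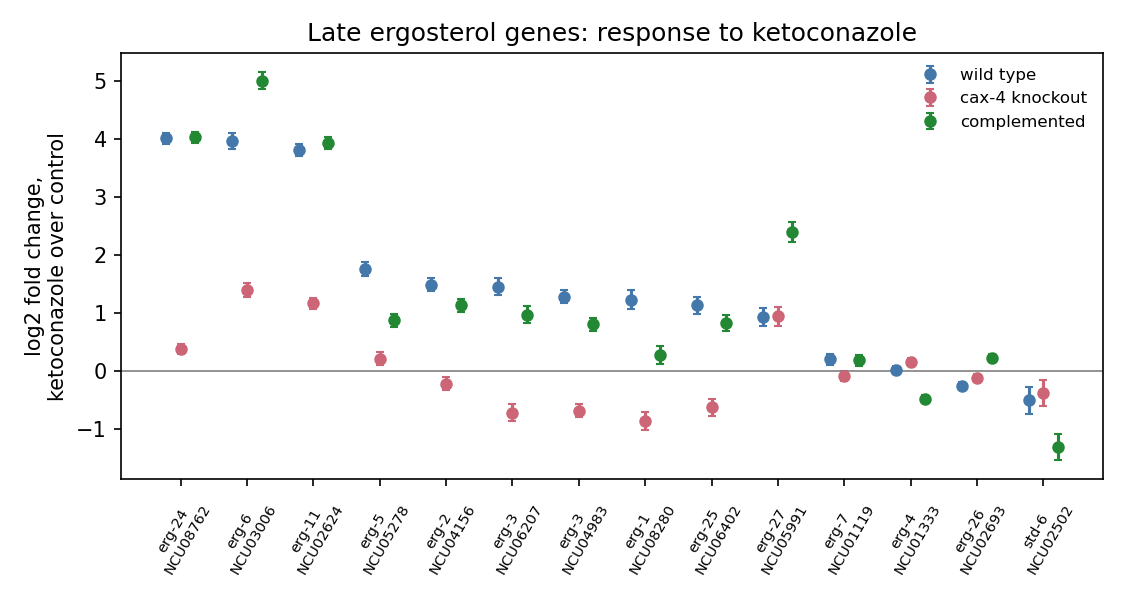
Log2 fold change of each of the 14 late ergosterol genes, ketoconazole over control (vertical axis), in the wild type, the cax-4 knockout and the complemented strain; points are edgeR estimates and bars their standard errors. For erg-24 the values are 4.01, 0.38 and 4.03 in that order, and for erg-6 they are 3.97, 1.40 and 5.01.

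Folding genes of the endoplasmic reticulum rose in the treated knockout, 17 of 21 with none fallen (camera adjusted p = 5.54e-04, and adjusted p = 0.211 with an estimated correlation). hsp70-6 (NCU09485), described as an endoplasmic reticulum chaperone of the HYOU1 kind, rose by 0.69 ± 0.085, and the glycoprotein glucosyltransferase gt24-1 (NCU02349), which checks the folding of N-glycosylated proteins, by 0.67 ± 0.089. Drug efflux genes had 13 risen and 3 fallen of 24 (camera adjusted p = 0.0428, and adjusted p = 0.211 with an estimated correlation), with abc-8 (NCU07546) at 1.94 ± 0.163, abc-5 at 1.84 ± 0.121 and the MRP-type transporter NCU02051 at 1.82 ± 0.109. This call was lost without control replicate 2 (camera adjusted p = 0.0506) or drug replicate 1 (0.0601). chol-14, the dolichol kinase gene, rose by 2.40 ± 0.167.

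Ribosomal protein genes fell in the knockout as well, 83 of 88 with 1 risen and a median of −0.63 by TMM (camera adjusted p = 6.25e-19, and adjusted p = 0.281 with an estimated correlation). By TMM crp-41 (NCU04779) fell by 0.80. Its fall was smaller on the FPKM scale, from a mean of 1258 to 934.6 FPKM. Of the oxidative phosphorylation genes 80 of 115 fell and 14 rose (camera adjusted p = 1.94e-08, and adjusted p = 0.281 with an estimated correlation). The plasma membrane proton pump gene pma-1 (NCU01680), which that list also holds, fell by 0.94. The mitochondrially encoded cob, cox-3 and the overlapping ndh-4 went the other way. On the FPKM scale each was higher in every treated knockout library than in every untreated one. Of the mevalonate genes 10 of 12 fell and 1 rose (camera adjusted p = 0.00432, and adjusted p = 0.4 with an estimated correlation), and of the fatty acid genes 5 of 6 fell and 1 rose (0.035, and adjusted p = 0.281 with an estimated correlation). acds-1, cel-2 and acc-1 fell by 1.82, 1.62 and 1.41. Wall genes had 29 higher and 12 lower of 56 and were not called as a set by camera (adjusted p = 0.119): ncw-5 (NCU00716) rose from 43.01 ± 1.99 to 693.8 ± 31.2 CPM, the chitinase gh18-5 (NCU04554) rose by 1.95 ± 0.163, and acw-6 (NCU03530) fell by 1.99.

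The largest rises in the knockout included NCU09636, described as a cytochrome P450 and at least 228-fold higher than in untreated libraries without a count, NCU00607 (10.01 ± 0.398) and mfs-29 (NCU07820, 7.89 ± 0.618). mkr-1 rose by 5.13 ± 0.428. The largest falls included rcd-1 (NCU05712), a gene of allorecognition cell death, from 38.29 ± 3.74 to 1.51 ± 0.419 CPM, and lao, by 3.72. In all, edgeR called 5259 genes, 2561 higher and 2698 lower, 1313 of them past 2-fold. On the FPKM scale the all-gene median lay at 0.31 and 78.8% of calls were higher, against 48.7%. The endoplasmic reticulum list had 18 higher and none lower adjusted over the list alone, and oxidative phosphorylation 14 and 82.

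The responses of the wild type and the knockout, which share no library, overlapped in part. Across 8404 genes their log2 fold changes had a Pearson correlation of 0.576 and a Spearman correlation of 0.501; genes are not independent replicates, so no p-value is given. 1388 genes were called higher in both strains where independent lists would share 793, and 1585 were called lower in both where independent lists would share 891. Another 702 genes were called in opposite directions.

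Whether the responses themselves differed was tested as the knockout's response minus that of the wild type. Of the 14 late ergosterol genes, 9 had a lower response in the knockout and none a higher one, with a median of −1.73 by TMM and −1.17 on the FPKM scale. The difference was −3.63 ± 0.123 for erg-24 (adjusted p = 4.57e-13, edgeR), −2.65 ± 0.134 for the overlapping erg-11, −2.57 ± 0.171 for erg-6 and −2.10 ± 0.224 for erg-1. It was −2.17 ± 0.207 for the overlapping NCU06207 copy of erg-3 and −1.98 ± 0.158 for its NCU04983 copy. For erg-25, erg-2 and erg-5 it was −1.76 ± 0.2, −1.71 ± 0.151 and −1.56 ± 0.163. sah-2 (NCU04731), described as related to the bHLH transcription factor CPH2, gave −1.76 ± 0.213. As a set the list was lower by camera (adjusted p = 2.19e-05), with adjusted p = 0.323 with an estimated correlation.

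Wall genes differed likewise. Of 56, 37 had a lower response in the knockout and 3 a higher one (camera adjusted p = 1.06e-07, and adjusted p = 0.323 with an estimated correlation), with a median of −0.51 by TMM that was −0.01 on the FPKM scale. ncw-2 stayed near its untreated level in the knockout, at 480.8 ± 34.3 CPM without drug and 461.4 ± 10.4 CPM with it, a difference in response of −3.81 ± 0.109. acw-9, acw-12 (NCU08171) and the glucanosyltransferase gene gh72-2 (NCU06781) gave −2.53 ± 0.127, −2.43 ± 0.13 and −1.91 ± 0.109. Some secreted enzymes that had risen in the wild type responded less, among them gh61-3 at −4.94 ± 0.199, the esterase ce1-3 (NCU04494) at −4.29 ± 0.193, gh61-9 (NCU05969) at −4.22 ± 0.13 and ply-2 at −5.28 ± 1.4. The glycoside hydrolase list had 7 higher and 16 lower responses of 42, with a median of −0.13 that turned to 0.19 on the FPKM scale (camera adjusted p = 0.0161, and adjusted p = 0.323 with an estimated correlation). The sphingolipid genes dcd (−1.89 ± 0.182) and gsl-6 (NCU06465, −1.96 ± 0.284) also had lower responses.

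Other genes had a higher response in the knockout. NCU06040, described as a major facilitator transporter, gave 5.69 ± 0.633 and mdr-2 2.95 ± 0.202, while abc-1 gave −2.42 ± 0.189. The fatty acid genes acc-1 and cel-1, which had fallen more in the wild type, gave 1.76 ± 0.297 and 1.39 ± 0.261. The chaperone genes hsp98 (NCU00104), hsp70-6 and grp78 gave 1.27 ± 0.184, 0.81 ± 0.119 and 0.65 ± 0.095. rcd-1 and NCU01849 gave −5.34 ± 0.222 and −4.67 ± 0.258. For chol-14 the difference was −0.07 ± 0.226 (adjusted p = 0.823, edgeR), with a sign that turned on the FPKM scale.

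A further pair of lists was called in this test, with directions that turned on the FPKM scale: ribosomal proteins, with 1 higher and 21 lower of 88 and a median of −0.15 against 0.41, and oxidative phosphorylation, with 15 higher and 57 lower of 115 and a median of −0.28 against 0.29. Their camera adjusted p values were 0.00492 and 8.4e-04, with adjusted p = 0.857 and adjusted p = 0.675 with an estimated correlation. edgeR called 4031 genes, 2067 with a higher and 1964 with a lower response in the knockout. On the FPKM scale the all-gene median lay at 0.5 and 86.9% of calls were higher, against 51.3%. The ribosomal list had 1 higher and 6 lower adjusted over the list alone, the wall list 3 and 38, and oxidative phosphorylation 16 and 61.

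Single genes differed between the untreated knockout and wild type in both directions. The invertase gene inv (NCU04265) stood at 487.4 ± 45.7 CPM in the knockout and 41.2 ± 20.4 CPM in the wild type (3.57 ± 0.27; adjusted p = 4.87e-08, edgeR). The sodium pump gene ena-1 (NCU05046) was 3.47 ± 0.141 higher, the transcription factor gene adv-1 (NCU07392) 3.37 ± 0.2 higher, and glyceraldehyde-3-phosphate dehydrogenase, gpd-1 (NCU01528), reached 16010 ± 1130 CPM (1.15 ± 0.134). The hydrophobin gene eas (NCU08457), whose product coats aerial hyphae and conidia, fell from 171.2 ± 13.4 to 6.58 ± 1.58 CPM (−4.70 ± 0.503). The cryptochrome gene cry (NCU00582) was 3.65 ± 0.813 higher (adjusted p = 0.00185, edgeR), from levels that varied between wild-type libraries (17.9 ± 18.6 CPM). con-8 (NCU09235), another conidiation gene, was lower by −2.25 ± 0.249, as were the carboxylic acid transporter gene sut-16 (NCU07607, −3.62 ± 0.136) and NCU04197, of the CipC family (−3.46 ± 0.142).

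Ergosterol genes went both ways without drug, 8 higher and 4 lower of 14 (camera adjusted p = 0.448). erg-1 was higher by 1.76 ± 0.161, the methyltransferase-like std-6 (NCU02502) by 1.45 ± 0.227 and erg-25 by 1.06 ± 0.142, whereas erg-6 was lower by −0.51 ± 0.12. Sphingolipid genes had 6 higher and 5 lower of 17 (camera adjusted p = 0.906), among them gsl-6 (1.92 ± 0.206) and a ceramidase gene, NCU10359 (−1.56 ± 0.133). In the dolichol and N-glycan list, cax-4 left out, 7 were higher and 9 lower of 24 (camera adjusted p = 0.906). The mannosyltransferase gene alg-11 (NCU06779) was higher by 0.74 ± 0.076 and alg-9 lower by −0.75 ± 0.123. ER folding genes had 2 higher and 9 lower of 21 (camera adjusted p = 0.176), with hsp70-6 at −0.80 ± 0.085 and gh31-2 (NCU04203), a glucosidase described as trimming N-glycans, at −0.75 ± 0.096.

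Ribosomal protein genes were higher in the knockout, 77 of 88 with 1 lower and a median of 0.53 by TMM and 0.12 on the FPKM scale (camera adjusted p = 2.16e-16, and adjusted p = 0.782 with an estimated correlation). Oxidative phosphorylation had 72 higher and 6 lower of 115, with a median of 0.25 that turned to −0.16 on the FPKM scale (camera adjusted p = 8.34e-06, and adjusted p = 0.782 with an estimated correlation). Adjusted over the list alone, these counts were the same. edgeR called 4820 genes, 2525 higher and 2295 lower, 1069 past 2-fold. On the FPKM scale the all-gene median was −0.33 and 17.9% of calls were higher, against 52.4%.

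With drug, several ergosterol and wall genes were lower in the knockout than in the wild type. erg-24 stood at 132.8 ± 8.11 CPM against 2092 ± 106 CPM (−3.98 ± 0.094; adjusted p = 1.3e-15, edgeR), erg-6 at −3.08 ± 0.128, the overlapping erg-11 at −2.26 ± 0.097, and the NCU04983 copy of erg-3 and erg-2 at −1.41 ± 0.113 and −1.27 ± 0.107. Of the 14 late ergosterol genes 10 were lower and 2 higher, one of the latter std-6 (1.58 ± 0.231) (camera adjusted p = 0.00112, and adjusted p = 0.523 with an estimated correlation). Of 56 wall genes 33 were lower and 6 higher (camera adjusted p = 2.85e-05, and adjusted p = 0.308 with an estimated correlation), including ncw-2 at −2.85 ± 0.08 and acw-12 at −2.62 ± 0.096. GPI anchor genes had 13 lower and 1 higher of 22 (camera adjusted p = 0.00205, and adjusted p = 0.3 with an estimated correlation), with the GPI mannosyltransferase gt22-1 (NCU00193) at −1.78 ± 0.124. Secreted glycoside hydrolases had 19 lower and 12 higher of 42 (camera adjusted p = 0.0112, and adjusted p = 0.3 with an estimated correlation), and gh61-9 was lower by −3.98 ± 0.099 and gh61-12 (NCU02344) by −3.98 ± 0.129.

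Single genes differed in both directions as well. The fasciclin-domain gene NCU00695 had no count in the treated knockout and was at least 2870-fold lower than in the wild type. The aquaporin gene aqp (NCU08052) was lower by −6.54 ± 0.27, the receptor-like gpr-21 (NCU05189) by −5.34 ± 0.225, con-10 (NCU07325) by −3.88 ± 0.376, con-8 by −3.15 ± 0.249 and abc-1 by −3.25 ± 0.13. Higher in the knockout were the sulfatase gene ars-1 (NCU06041, 5.03 ± 0.248), NCU06040 (5.19 ± 0.233), mdr-2 (2.52 ± 0.149) and grp78 (0.83 ± 0.067). The mitochondrially encoded cox-3 (NCU16003) was higher by 1.66 ± 0.109. Ribosomal protein genes were again higher, 67 of 88 with 7 lower (camera adjusted p = 6.7e-07, and adjusted p = 0.847 with an estimated correlation). edgeR called 5333 genes, 2769 higher and 2564 lower, 1656 past 2-fold; on the FPKM scale the all-gene median was 0.16 and 65.6% of calls were higher, against 51.9%. Adjusted over the list alone, 2 ergosterol genes were higher and 11 lower, 7 and 33 wall genes, 1 and 14 GPI anchor genes, 12 and 21 glycoside hydrolases, and 68 and 7 ribosomal protein genes.

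The complemented strain held cax-4 RNA at 16.8% of the wild-type FPKM without drug and 23% with it. It served to ask whether expression returned towards the wild type when cax-4 was restored in part. Several of its ergosterol genes rose with the drug: erg-6 rose by 5.01 ± 0.141, erg-24 by 4.03 ± 0.095 and the overlapping erg-11 by 3.93 ± 0.105 (adjusted p = 2.15e-15, edgeR). Of the 14 genes 10 rose and 2 fell (camera adjusted p = 0.00287, and adjusted p = 0.305 with an estimated correlation), the same counts as when adjusted over the list alone. ncw-2 rose by 3.39 ± 0.082 and gh61-9 by 2.54 ± 0.093. In total 5869 genes were called, 2938 higher and 2931 lower. Set against the response of the wild type, the difference was 0.02 ± 0.119 for erg-24 (adjusted p = 0.887, edgeR) and 0.12 ± 0.132 for erg-11 (adjusted p = 0.486), while erg-6 responded more, by 1.04 ± 0.169, as did erg-27 (1.47 ± 0.231) and erg-26 (0.48 ± 0.096). Lower responses than in the wild type were called for erg-1 (−0.96 ± 0.222), erg-5 (−0.89 ± 0.163), erg-4 (NCU01333, −0.51 ± 0.094) and the NCU04983 copy of erg-3 (−0.48 ± 0.156), the last a call lost without drug replicate 3 of the complemented strain (adjusted p = 0.0535, edgeR). Of the 14 genes 3 thus responded more and 4 less (3 and 7 adjusted over the list alone), with a median of −0.34 and camera adjusted p = 0.597.

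Compared directly under drug, the knockout was lower than the complemented strain for erg-24 (−3.39 ± 0.092), the overlapping erg-11 (−2.95 ± 0.1), erg-6 (−2.91 ± 0.127), ncw-2 (−3.16 ± 0.081) and gh61-9 (−3.92 ± 0.099). Of the late ergosterol genes 12 of 14 were lower and 1 higher (camera adjusted p = 1.11e-04, and adjusted p = 0.271 with an estimated correlation), and of the wall genes 40 of 56 were lower and 4 higher (camera adjusted p = 1.46e-07, and adjusted p = 0.2 with an estimated correlation). GPI anchor genes had 15 lower and 1 higher of 22, with a median of −0.51 that turned to 0.12 on the FPKM scale (camera adjusted p = 8.32e-04, and adjusted p = 0.2 with an estimated correlation). Adjusted over the list alone, the GPI anchor list had 2 higher and 15 lower, and the ergosterol and wall counts were the same. edgeR called 5884 genes, 3043 higher and 2841 lower; on the FPKM scale the all-gene median was 0.55 and 82.3% of calls were higher, against 51.7%. With drug the complemented and wild-type strains still differed in 5622 genes, 2781 higher and 2841 lower in the complemented strain (an all-gene median of −0.39 and 20.8% higher on the FPKM scale, against 49.5%). abc-1 was lower by −1.82 ± 0.122 and erg-24 by −0.59 ± 0.084, and erg-11 was higher by 0.69 ± 0.093.

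Without drug, the complemented strain differed from the wild type in more genes, 6156 (3189 higher and 2967 lower, 2326 past 2-fold), with 22.5% higher on the FPKM scale against 51.8% and an all-gene median there of −0.44. Conidiation and light-related genes were higher: the cryptochrome gene cry (NCU00582) by 6.76 ± 0.926, the blue-light receptor gene vvd (NCU03967) by 5.98 ± 0.97, eas by 2.34 ± 0.418 and con-8 by 1.72 ± 0.236. Of 25 conidiation genes 19 were higher and 1 lower (camera adjusted p = 3.75e-04, and adjusted p = 0.803 with an estimated correlation). That list includes vvd and carotenoid genes, which light also induces. All 32 called proteasome genes, of 36, were lower (camera adjusted p = 1.13e-06, and adjusted p = 0.803 with an estimated correlation). Counts adjusted over the list alone were the same for both. erg-1 was higher by 2.04 ± 0.162 and erg-6 lower by −1.21 ± 0.123. Genes that light induces in this fungus were higher as well: 5 of 6 markers, listed before their values were read, were called by edgeR, from sub-1 (2.29 ± 0.287, adjusted p = 4.18e-06) to bli-4 (5.75 ± 1.007, adjusted p = 1.82e-04).

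**Figure D4:**
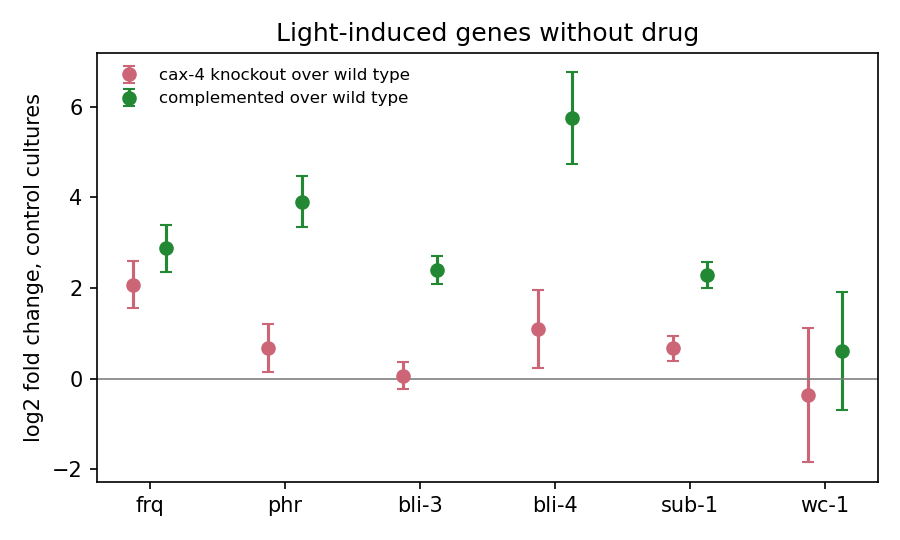
Log2 fold change without drug (vertical axis) of 6 light-induced genes in the cax-4 knockout and in the complemented strain, each over the wild type; points are edgeR estimates and bars their standard errors. In the complemented strain 5 of the 6 were called higher, and wc-1 (0.61) was not.

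Between the untreated knockout and complemented strain 5278 genes were called, 2597 higher and 2681 lower in the knockout (62.9% higher on the FPKM scale, against 49.2%). Lower in the knockout were eas (−7.04 ± 0.543), con-8 (−3.97 ± 0.264) and cry (−3.11 ± 0.772), and ena-1 was higher (2.59 ± 0.136).

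A gene was counted as moved back where it was called the same way in the knockout against both other strains. With drug this held for 3131 of the 5333 genes called between knockout and wild type (58.7%), where independent lists would share 1870, and 1326 of them were not called between the complemented strain and the wild type. Without drug it held for 1718 of 4820 genes (35.6%), where independent lists would share 1512, and 798 of them were not called between complemented and wild type. Both comparisons use the same knockout libraries. With drug their log2 fold changes correlated at 0.627 across genes, which are not independent replicates, and simulated unchanged groups gave 0.487; the covariance was 0.86 against a simulated 0.032. Without drug the correlation was 0.172 against a simulated 0.487, and the covariance 0.142 against 0.033. The simulated groups held no strain effect, so their lack of shared calls in either direction was fixed beforehand. Their correlation is that of noise with shared libraries and is no reference for strains that differ. As 3 libraries cannot be halved into parts of 2, part of the excess can come from the shared libraries. A difference particular to the knockout also enters both comparisons, whatever its source. The excess over independent lists therefore does not show a return by itself. Genes moved back also include some that went past the wild type. Without drug eas and con-8 were lower in the knockout and higher in the complemented strain than in the wild type. Genes called the same way in the knockout and the complemented strain, each against the wild type, numbered 3329 without drug, where independent lists would share 1768, and 2642 with it, where they would share 1783. These shared the wild-type libraries: the correlation was 0.594 without drug (simulated 0.512, covariance 0.602 against 0.035) and 0.351 with it (simulated 0.478, covariance 0.401 against 0.032).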

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

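Of the tests of the ergosterol pattern below, the one for a generally weaker response was chosen before its result was seen, and the tests on the FPKM scale and in the complemented strain after.

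The drug response of 4031 genes differed between knockout and wild type, which marked them through a test of the difference itself (edgeR). Of the 18 lists camera called 5 in this difference, and each of those calls was lost with adjusted p between 0.323 and 0.857 with an estimated correlation. The median differences were −1.73 for late ergosterol genes, −0.51 for wall genes, −0.28 for oxidative phosphorylation, −0.15 for ribosomal proteins and −0.13 for secreted glycoside hydrolases. The last 3 medians turned to 0.29, 0.41 and 0.19 on the FPKM scale, in that order. The wall median all but vanished on that scale, as given above, while the ergosterol median was −1.17.

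Among single genes, the difference in response marked erg-24 (−3.63), erg-11 (−2.65, overlapping), erg-6 (−2.57), erg-3 (NCU06207, −2.17, overlapping; NCU04983, −1.98), erg-1 (−2.10), erg-25 (−1.76), erg-2 (−1.71) and erg-5 (−1.56). It marked the wall genes ncw-2 (−3.81), acw-9 (−2.53), acw-12 (−2.43) and gh72-2 (−1.91), and the secreted enzymes ply-2 (−5.28), gh61-3 (−4.94), ce1-3 (−4.29) and gh61-9 (−4.22). Transport and regulation were represented by NCU06040 (5.69), mdr-2 (2.95), abc-1 (−2.42) and sah-2 (−1.76), lipid synthesis by acc-1 (1.76), cel-1 (1.39), dcd (−1.89) and gsl-6 (−1.96). The chaperone genes hsp98 (1.27), hsp70-6 (0.81) and grp78 (0.65) were marked too, as were rcd-1 (−5.34) and NCU01849 (−4.67).

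Of 100 splits of the samples, the real one with its 4031 and 1 other called as many genes. The other split called 5830 genes and exchanged the control and drug labels of all 6 wild-type libraries, which adds the responses of both strains where the real split subtracts them. Such splits hold real drug effects, so the count of splits, here and for the complemented strain, cannot decide whether chance made the difference.

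The weak response of ergosterol genes in the knockout was weighed against technical causes. Scaling between libraries does not account for it: the median difference was −1.17 on the FPKM scale, where the median of all genes was 0.5, and 9 of 14 genes were still called lower. For some genes part of the difference lay in the untreated level. Without drug erg-1, erg-25 and the NCU06207 copy of erg-3 were higher in the knockout, by 1.76, 1.06 and 0.95 (edgeR). The NCU04983 copy, erg-5, erg-2 and erg-11 were higher by less. In contrast erg-24 and erg-6 were lower there, at −0.35 and −0.51. In wild-type controls 1 to 3 some of these levels rose with replicate number, as vvd did. They were 97.98, 131.4 and 150.8 FPKM for erg-1 and 1295, 1729 and 1950 FPKM for erg-25. For the NCU06207 copy of erg-3 they were 249.2, 330.5 and 378.8 FPKM. Every untreated knockout library lay above them. Whether the source of this replicate trend also shaped the untreated differences was not tested. With drug erg-1 held 222.4 to 235.8 FPKM in the knockout and 210.8 to 287.8 FPKM in the wild type. The 10 genes that had risen in the wild type had a median response of 0 in the knockout. This lay at percentile 1.24 of 10000 random sets of genes with a like rise, whose median was 0.73. Genes of a shared pathway move together while the sets were drawn at random, so this percentile cannot exclude a generally weaker response. In the complemented strain the difference from the wild type lay closer to 0 for 10 of 14 genes, which is in line with loss of cax-4 as the source. That strain also differed from the wild type in 6156 genes without drug, so other differences between the strains remain possible.

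The drug response of 3778 genes differed between complemented strain and wild type, by the same test of the difference in response. The lists marked were conidiation (median −0.76, 11 of 25 lower), ribosomal proteins (−0.33, 55 of 88 lower), endoplasmic reticulum folding (0.46, 13 of 21 higher), GPI anchors (0.22, 9 of 22 higher and 3 lower), iron uptake (0.96, 4 of 5 higher) and the proteasome (0.21, 16 of 36 higher). Their camera adjusted p values were 0.021, 1.21e-08, 7.98e-05, 0.0307, 0.0199 and 0.00166, and between adjusted p = 0.219 and adjusted p = 0.542 with an estimated correlation. The conidiation list includes vvd, al-1, al-2, al-3 and cao-2, which light also induces, so it is not separate from the light-induced genes. Of 6 other light-induced markers, 5 were called lower in this difference by edgeR. These were frq (−2.32), phr (−2.76), bli-3 (−2.03), bli-4 (−5.02) and sub-1 (−1.24, and −0.79 without wild-type drug replicate 3). The remaining marker, wc-1, was called higher (5.28), a call lost without wild-type control replicate 1 (adjusted p = 0.386, edgeR). The conidiation call was lost without wild-type control replicate 1 (0.0591) or wild-type drug replicate 3 (0.0646). Adjusted over the list alone, 62 ribosomal genes were lower, 14 folding genes higher and 10 GPI anchor genes higher. Genes marked were vvd (−4.27), mdr-2 (2.30), abc-1 (−1.46), erg-27 (1.47), erg-6 (1.04), erg-1 (−0.96), erg-5 (−0.89), erg-4 (−0.51), erg-26 (0.48), erg-3 (NCU04983, −0.48), ncw-2 (−0.36) and gh61-9 (−0.34). The call of erg-3 was lost without complemented drug replicate 3 (adjusted p = 0.0535, edgeR), and that of gh61-9 without any one of 6 of the 12 libraries.

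For this difference 6 of 100 splits, the real one included, called as many genes, with 6223 the most in another split, so chance is not excluded by this count of splits. All 5 of those others exchanged 4 to 6 of the 6 wild-type labels and none of the complemented strain. They mostly add the drug responses of both strains.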

How the results depend on the processing

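Counts of called genes stayed within 1.5 times under DESeq2, RLE factors, either filter, a fit on the compared groups, the replicate block and both FPKM fits. At a 2-fold threshold they fell to 1661, 1313 and 2212 for the drug in wild type, knockout and complemented strain; 1069 and 1656 for knockout against wild type without and with drug; 2326 and 1795 for complemented against wild type; 1461 and 2295 for knockout against complemented; and 1380 and 1156 for the differences of response. Without 1 library the counts, in that order, were 4978–5253, 4741–4962, 5499–5622, 4210–4802, 4904–5307, 5749–6050, 5159–5612, 4755–5087, 5519–5619, 3611–4065 and 3357–3817. With an estimated correlation 0 lists were called in every comparison; fry called 13 and 17 for the drug in knockout and complemented strain, 8 and 10 for knockout against wild type, 13 and 15 for complemented against wild type, 11 and 17 for knockout against complemented, and 8 and 12 for the differences. The ribosomal list of the knockout's difference was lost under fry (adjusted p = 0.0797).

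On the FPKM scale with pseudocounts 1 and 0.1, medians of called lists turned for oxidative phosphorylation in knockout against wild type without drug (−0.16, −0.16), wall genes in complemented against wild type with drug (−0.11, −0.11), GPI anchors (0.12, 0.12) and glycoside hydrolases (0.15, 0.17) in knockout against complemented with drug, and ribosomal proteins (0.41, 0.42), oxidative phosphorylation (0.29, 0.29) and glycoside hydrolases (0.19, 0.32) in the knockout's difference. Of the 67 medians of called lists, a further 53 and 50 moved by more than 0.1 without turning, and 7 and 10 stayed the same, with pseudocounts 1 and 0.1. The correlation of wild-type and knockout responses was 0.616 among genes of at least 10 FPKM and 0.507 (Spearman 0.461) with DESeq2, and 874 genes were higher in both at 10 FPKM, where fewer genes were tested. Genes moved back numbered 211 without and 885 with drug at 2-fold. The cause was not tested.

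Of 3555 alternatives for the 217 printed gene results 3473 kept their call, 73 were weaker (34 of them at the 2-fold threshold), 2 stronger and 7 reversed. The reversed values were not called: chol-14 in the knockout's difference (0.40 and 0.47 on the FPKM scale, 0.02 without wild-type control replicate 3, 0.01 without knockout drug replicate 2, with −0.17 to 0.02 over all left-out libraries) and erg-24 in the complemented strain's difference (−0.01, −0.01 and −0.08 without 1 library, with −0.08 to 0.10 over all). Over all 1559 results of the naming rule 93.2% of 23478 alternatives kept the call, 665 were weaker, 371 stronger and 561 reversed; 235 results reversed at least once, 77 of them called. The text's choice of genes is thus steadier than the rule's. The list medians under other scalings and the left-out libraries for lists, shared response and return were chosen after seeing the data.

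With a replicate block the gene counts, in the order above, were 5482, 5355, 5953, 4946, 5451, 6152, 5663, 5386, 5954, 4234 and 3987, and drug efflux was no longer called in wild type (camera adjusted p = 0.052) or knockout (0.059). Samples sharing a number had a median residual correlation of 0.03 over 45 pairs (−0.14 to 0.372), so the numbers were not taken as pairs. In the wild type, however, control and drug libraries of replicates 1, 2 and 3 correlated at 0.355, −0.085 and 0.372. Control replicate 1 with drug replicate 3 stood at −0.391, and control replicate 3 with drug replicate 1 at −0.358. Replicates 1 and 3 gave the same signs, at smaller values, in all pairs that involved knockout libraries and wild-type or other knockout libraries. Wild-type and knockout drug replicate 3 correlated at 0.269, and knockout control and drug replicate 3 at 0.172. Knockout drug replicate 3 stood at −0.192 with wild-type drug replicate 1 and at −0.119 with knockout control replicate 1. Replicate 2 gave mixed signs. A shared replicate effect in the wild type and the knockout is therefore not excluded. Of the simulated changes, those of 1.5-fold were recovered least often.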

Other observations

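Of the tests in this part, those on mislabelling and abundant genes were chosen after their results were seen, and the one on light markers before; the pattern of carotenoid genes replaced a planned pattern of ribosomal genes before either was tested.

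Without drug the complemented strain held more RNA of several genes for carotenoid synthesis than the wild type did. Carotenoids give the conidia of this fungus their orange colour. By edgeR, phytoene desaturase, al-1 (NCU00552), was higher by 5.01 ± 1.017 (59.7 to 1920 CPM; adjusted p = 6.09e-04), and phytoene synthase, al-2 (NCU00585), by 4.41 ± 0.6 (281 to 5990 CPM). The carotenoid oxygenase gene cao-2 (NCU11424) was higher by 4.28 ± 0.613 and al-3 (NCU01427), for geranylgeranyl diphosphate, by 1.14 ± 0.397 (adjusted p = 0.0188). The al-3 call was lost on the FPKM scale (0.56, adjusted p = 0.153) and without wild-type control replicate 1 (adjusted p = 0.0528) or 2 (0.0598). In the knockout al-2 was higher by 1.68 ± 0.536 (adjusted p = 0.0162, edgeR), a call lost without wild-type control replicate 1 (0.074) or 2 (0.0599) or knockout control replicate 3 (0.0563), while al-1 stood at 1.11 ± 0.883 (adjusted p = 0.3). These genes were chosen after their values were seen, and not every carotenoid gene was higher. Without drug ylo-1 (NCU04013), a carotenal oxygenase gene, held 87.57 to 99.5 FPKM in the complemented strain and 115.1 to 127.6 FPKM in the wild type. On that scale the all-gene median was −0.44.

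The carotenoid pattern was weighed against a difference in light between cultures, since light induces these genes. Of 6 other light-induced genes 5 were called higher by edgeR: frq (2.88), phr (3.91), bli-3 (2.40), bli-4 (5.75) and sub-1 (2.29), the last also in the sexual development list; wc-1 stood at 0.61 (0.11 to 2.29 without 1 library). This is consistent with more light-induced transcription in those cultures and would also arise from a strain that responds more to light, which the test cannot separate. The wild-type libraries themselves varied widely, as vvd (59.7 ± 67.9 CPM) shows. Its level rose with replicate number, at 2.72, 16.28 and 57.29 FPKM in wild-type controls and 67.49, 103.9 and 310.2 FPKM with drug. Replicate 3 also held the most vvd in every other group except the treated complemented strain. In the untreated knockout frq was called as the only one of the 6 (2.08), and vvd, outside these markers, was higher by 3.18 (adjusted p = 0.00637, edgeR). With the drug, 4 of the 6 rose in the wild type and 4 in the knockout, where the values were 1.64 for phr, 0.90 for bli-3, 1.10 for sub-1 and 4.56 for wc-1. In the complemented strain bli-3 (−2.33) and bli-4 (−2.08) fell with the drug and wc-1 (6.31) rose. In the knockout the phr and bli-3 calls were lost without control replicate 1 (adjusted p = 0.0533 and 0.0567, edgeR) or 2 (0.0575 and 0.059) or drug replicate 3 (0.0781 and 0.0818). The bli-4 call of the complemented strain was lost without any one of 5 of its 6 libraries (adjusted p = 0.0803 to 0.112, edgeR).

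Without drug the complemented strain stood farther from the wild type than the knockout did, with 2326 against 1069 genes past 2-fold. The 10 most abundant genes of each library took 19.96 to 20.66% of the counts in the untreated complemented strain, 15.01 to 15.72% in the knockout and 11.69 to 13.7% in the wild type. A few abundant genes shift all others by the same amount and leave the spread of fold changes as it is, so they do not account for the wider spread in the complemented strain. The interquartile range of log2 fold changes over all genes was 1.18 there and 0.78 in the knockout, a ratio of 1.52 (1.47 to 1.59 without 1 control library, and 1.58 on the FPKM scale). A planned test that left out the 20 most abundant genes moved the numbers too little to decide (2323 and 1062). A mislabelled sample is unlikely, since the complemented libraries held 99 to 123 counts of cax-4, the wild type 515 or more and the knockout 0. Strain background, light and the partial level of cax-4 remain possible and were not separated here.

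For the other comparisons only 10 splits of the samples exist, too few for a share under 0.05. In each only 1, the real one, called as many genes. The real numbers and the highest of the other splits were 5378 and 116 for the drug in the wild type, 5259 and 0 in the knockout and 5869 and 0 in the complemented strain. For knockout against wild type they were 4820 and 1 without drug and 5333 and 0 with it. For complemented against wild type they were 6156 and 0 without and 5622 and 0 with drug, and for knockout against complemented 5278 and 1, and 5884 and 0.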
